A study of Homo sapiens with 99 samples.

How the data were processed

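Polyadenylated RNA from cores of archived leiomyosarcoma tissue was selected with oligo(dT), sheared, converted to cDNA and sequenced for 36 bases, per the labels' protocols. The genome build was hg19, per the submitters' processing notes; the aligner, the counter and the gene annotation are not given in the sources used here. The authors deposited 1 table of 22144 gene symbols by 99 libraries in RPM (tags scaled to a total of 1000000 per library): each library sums to 1000000 to within rounding. The 26 symbols that are whole numbers, as a spreadsheet makes of some gene names, were tested and never named. The reference used here is of another build, so no coordinates are given.

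Values in the deposited RPM are whole multiples of the value of 1 tag, so tag counts were recovered for 97 libraries, where 100% of values came out whole within 0.1 tags at the lowest. For the other 2 libraries the step was too close to 1 to tell, and they stayed out of the count test only, which used 93 labelled libraries. Depth limits low genes most: in the shallowest library 1 tag is worth over 10 RPM. The highest correlation between any pair of libraries was 0.988, so none was counted as a duplicate.

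Genes with at least 1 RPM in at least 26 libraries, the size of the smallest subtype, were tested (14110). log2(RPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend and robust) over the 95 labelled libraries in 1 fit, two-sided, with Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(RPM + 1) scale, which understates the change of low genes. The 28 gene lists, the tests, the rule for named genes and most of the alternatives were fixed before the data were examined. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 75 tests. List scores of 27 lists were compared by two-sided permutation tests with 100000 resamples, adjusted over 81 tests. Library measures were tested in the same way, 6 as planned and 15 added after seeing the data (depth, RNF168, silent families and genes in 50000 tags). The total per library is fixed by the scaling, so its planned test was void. SAM was written out here, since its package is not installed. Relations between scores were computed within each subtype only.

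Named genes were, per contrast and direction, the 6 of largest fold change among called genes with a mean of at least 5 RPM in the higher subtype; per subtype, the 8 with the largest smaller-of-2 fold change among genes above both others; per list, the 4 members with the smallest adjusted p of the moderated F test; and the study's marker LMOD1. Some genes that the rule picks are not named in the text. Genes of the Y chromosome, XIST, TSIX, unnamed rows and immunoglobulin or T cell receptor segments were never named. RNF168 and the olfactory receptor genes were singled out after their values were seen, and the 4 other silent families after that but before their own values were seen.

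The fits were tested on simulated data for the 14110 genes, with a dispersion of 0.64 estimated from these libraries. With 100 genes changed 2-fold in subtype III, limma recovered 21% against subtype I and 30% against subtype II; of 100 changed 4-fold it recovered 94% in both. With changes in subtype I and the contrast against subtype II it recovered 28% and 98%. It also called genes that were left unchanged. With changes in subtype III these false calls numbered 22 against subtype I and 33 against subtype II. With changes in subtype I they numbered 6 against subtype II and 10 against subtype III. With changes in subtype II they numbered 3 against subtype I and 10 against subtype III. In each simulated contrast with subtype III the false calls were a larger share of calls than the adjusted p threshold allows. The counts of called genes in contrasts with subtype III carry that limit. Alternatives used other pseudocounts, filters, scalings, covariates and tests, among them edgeR 4.0.16 on the recovered tags, and each number series alone. Alternatives added after seeing the data left out RNF168, shallow libraries or genes with A or T runs, or took the olfactory receptor total as a covariate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.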

Results

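The series holds 99 leiomyosarcomas, malignant tumours with smooth muscle differentiation, archived as formalin-fixed and paraffin-embedded tissue and profiled by 3SEQ, a method that sequences a short tag near the 3′ end of polyadenylated transcripts. The labels place 31 tumours in subtype I, 38 in subtype II and 26 in subtype III, and 4 carry no subtype. The submitters defined the subtypes by clustering the expression of these same tumours, so the p-values given here measure how far labelled groups separate and are no independent evidence that groups exist. The labels do not say that each sample came from a different donor, so p-values measure the spread between these samples. The comparisons ask which genes differ between the subtypes. Libraries held between 70246 and 8890877 tags, with a median of 1407340; the numbers of 2 libraries, near 1000000, are uncertain.

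The libraries of subtype III were shallower than the others and carried more tags from genes that are silent in most tissues. The median number of tags was 1956897 in subtype I, 1580085 in subtype II and 616082.5 in subtype III (adjusted p = 0.000525 for I against III and 0.00233 for II against III on the log2 scale, permutation test). RNF168, which encodes a ubiquitin ligase of the DNA damage response, took a median of 3.61% of tags in subtype I, 7.91% in subtype II and 20.3% in subtype III, and was the highest gene in 65 of the 99 libraries. Its mean share was 24.1% ± 21.8 (SD, n = 26) in subtype III against 10.5% ± 16.7 (SD, n = 31) in subtype I, with an adjusted p of 0.0133, and 11.6% ± 11.9 (SD, n = 38) in subtype II, with an adjusted p of 0.0062. Keratin associated, taste receptor, vomeronasal and beta defensin genes together had a median of 48.4 RPM in subtype I, 48.2 in subtype II and 174 in subtype III (adjusted p = 3.75e-05 for both contrasts with subtype III, permutation test). The number of genes at 1 RPM or more had means of 11779 ± 1848 (SD, n = 31), 11658 ± 1406 (SD, n = 38) and 11906 ± 2343 (SD, n = 26) in subtypes I, II and III, and no contrast passed the test, the smallest adjusted p being 0.822. At an equal depth of 50000 tags other than RNF168, subtype III had more genes than subtype I (difference -707, adjusted p = 0.000579) and subtype II (-776, adjusted p = 3.75e-05), a measure added after seeing the data. The share of tags in the 50 highest genes was 40.4% ± 12.5 (SD, n = 31), 39.1% ± 9.84 (SD, n = 38) and 47.1% ± 18.4 (SD, n = 26), with a smallest adjusted p of 0.168.

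**Figure D1:**
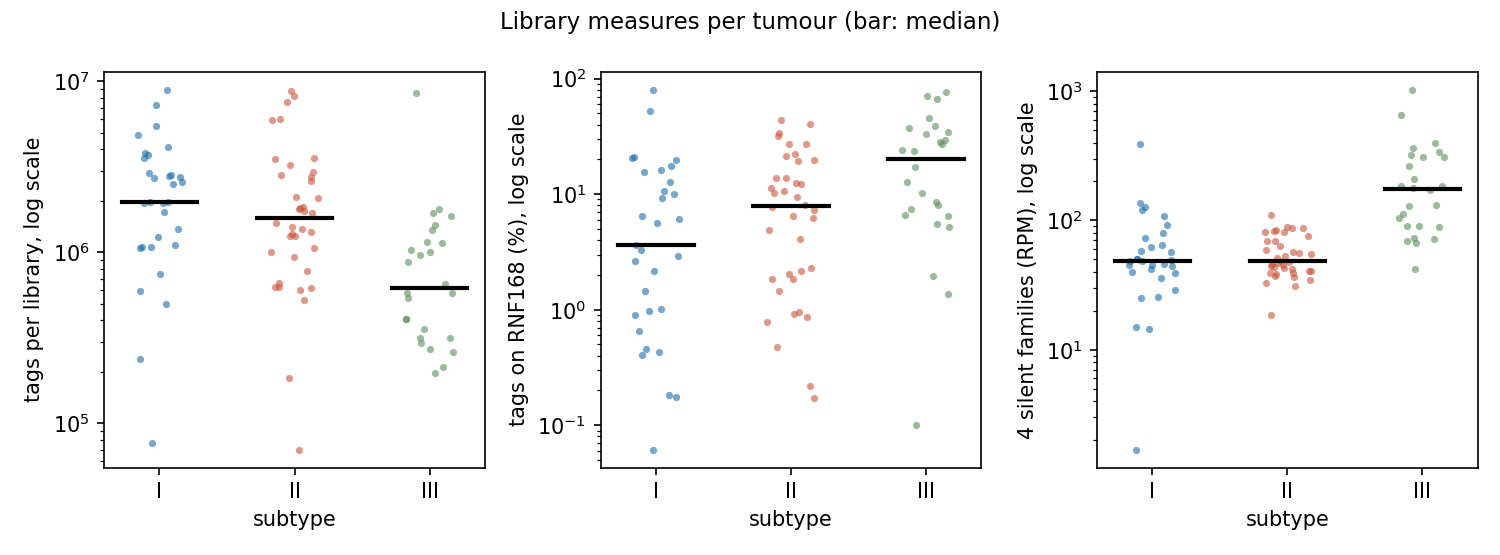
Tags per library, the percentage of tags on RNF168 and the summed RPM of 4 silent gene families, each on a log axis, with 1 point per tumour and a bar at the median of subtypes I, II and III. Subtype III has the lowest median number of tags (616082.5) and the highest median share on RNF168 (20.3%).

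The specimen numbers in the titles fell into a low, a middle and a high series, which were unevenly spread over the subtypes (permutation test of chi-square, p = 0.00276). Subtype I had 12, 14 and 5 tumours in these series, subtype II had 16, 12 and 10, and subtype III had 11, 1 and 14. Within the low series the median tags on RNF168 were 0.675% in subtype I, 1.83% in subtype II and 8.60% in subtype III, and within the high series 17.7%, 12.5% and 27.9%. The 4 silent families had medians of 177 RPM in subtype III against 56.3 and 48.2 in subtypes I and II within the low series, and 158 against 15.1 and 48.9 within the high series.

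Subtypes I and II differed most in genes of the smooth muscle contractile apparatus, which were higher in subtype I, and in genes of the extracellular matrix, which were higher in subtype II. MYH11, the smooth muscle myosin heavy chain, had a median of 2803 RPM in subtype I and 7.84 RPM in subtype II, a log2 fold change of 7.47 (SE 0.59, adjusted p = 6.6e-18), and all 31 subtype I tumours lay above the subtype II median. The smooth muscle score, the mean log2(RPM + 1) of the 25 listed genes, was 7.95 ± 0.82 (SD, n = 31) in subtype I and 5.09 ± 1.11 (SD, n = 38) in subtype II (adjusted p = 8.1e-05, permutation test, from the smallest p that the resamples can give). The extracellular matrix score of 20 genes was 6.26 ± 0.78 (SD, n = 31) in subtype I and 7.65 ± 0.79 (SD, n = 38) in subtype II, with the same adjusted p. Of 14110 genes tested with limma, 597 were higher and 625 lower in subtype I.

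Other genes with large fold changes in favour of subtype I were CNN1, encoding calponin, at 5.29 (SE 0.55), LMOD1, encoding the actin nucleator leiomodin 1, at 5.12 (SE 0.45), ACTG2, the enteric smooth muscle actin, at 4.99 (SE 0.54), ASB2 at 4.83 (SE 0.52) and JPH2, a junctional membrane protein, at 4.56 (SE 0.52). Of the 25 smooth muscle genes 22 were higher in subtype I and none lower, and 24 were higher when adjusted over the list alone. KCNMB1, a potassium channel subunit, rose by 3.22 (SE 0.33) and SYNPO2 by 3.19 (SE 0.35). MYOCD, the transcriptional coactivator that drives contractile genes, rose by 2.21 (SE 0.28). Of 10 hormone receptor and uterine genes 1 was higher in subtype I and none lower, and 2 were higher when adjusted over the list alone. PLIN4, a lipid droplet protein of the adipocyte list, rose by 3.74 (SE 0.46) and LIPE, a lipase, by 1.26 (SE 0.31).

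In the other direction, the largest changes in favour of subtype II were LRRC15 at 3.64 (SE 0.62), PCOLCE, an enhancer of procollagen processing, at 3.18 (SE 0.39), the protease MMP9 at 3.04 (SE 0.61), TMEM119 at 2.95 (SE 0.49), PYCR1, an enzyme of proline synthesis, at 2.71 (SE 0.36), and CREB3L1, a transcription factor, at 2.68 (SE 0.45). Of the 20 extracellular matrix genes 15 were higher in subtype II and none lower, and 18 were higher when adjusted over the list alone. COL1A1 was higher by 2.33 (SE 0.38) and COL1A2, which encodes the other chain of collagen I, by 1.97 (SE 0.34). Of 18 macrophage genes 5 were higher in subtype II and none lower, and 14 were higher when adjusted over the list alone. FCGR3A, an Fc receptor, had medians of 2.58 RPM in subtype I and 7.33 RPM in subtype II, and LAPTM5, a lysosomal protein of blood cells, was higher by 1.49 (SE 0.40). Of 13 Wnt and ROR genes 4 were higher in subtype II, and 1 was lower and 5 higher when adjusted over the list alone. WNT5B was higher by 2.03 (SE 0.29) and FZD1, a Wnt receptor, by 1.00 (SE 0.31). Of 10 unfolded protein response genes 4 were higher in subtype II, and 7 when adjusted over the list alone, where 1 was lower. They included SDF2L1 at 1.09 (SE 0.30) and CALR, a chaperone, at 0.82 (SE 0.27).

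The camera test called 8 of 25 lists between subtypes I and II. Smooth muscle (adjusted p = 5.27e-60) and hormone receptor genes (adjusted p = 0.0123) were higher in subtype I. Extracellular matrix (2.78e-18), macrophage (9.87e-08), unfolded protein response (0.00233), MHC class II (0.00687), Wnt and ROR (0.0132) and ribosomal protein genes (0.0318) were higher in subtype II. With an estimated correlation between members only smooth muscle and extracellular matrix were called, with adjusted p = 5.53e-05 and 0.0106, and the adjusted p of the other 6 lists ran from 0.517 to 0.864. Within the low, middle and high series the smooth muscle score differed by 2.99, 3.67 and 1.36, and the high series, with 5 subtype I tumours, did not pass the test (exact permutation test, adjusted p = 0.103). The extracellular matrix score differed by -1.31, -1.46 and -1.22 and did not pass in the high series either (exact permutation test, adjusted p = 0.0528). The counts within the high series were 92 higher and 634 lower genes. Of 40 ribosomal protein genes 2 were lower in subtype I and none higher, and 4 when adjusted over the list alone. Their score did not pass (-0.20, adjusted p = 0.355, permutation test) and differed by 0.33 in the other direction within the low series.

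**Figure D2:**
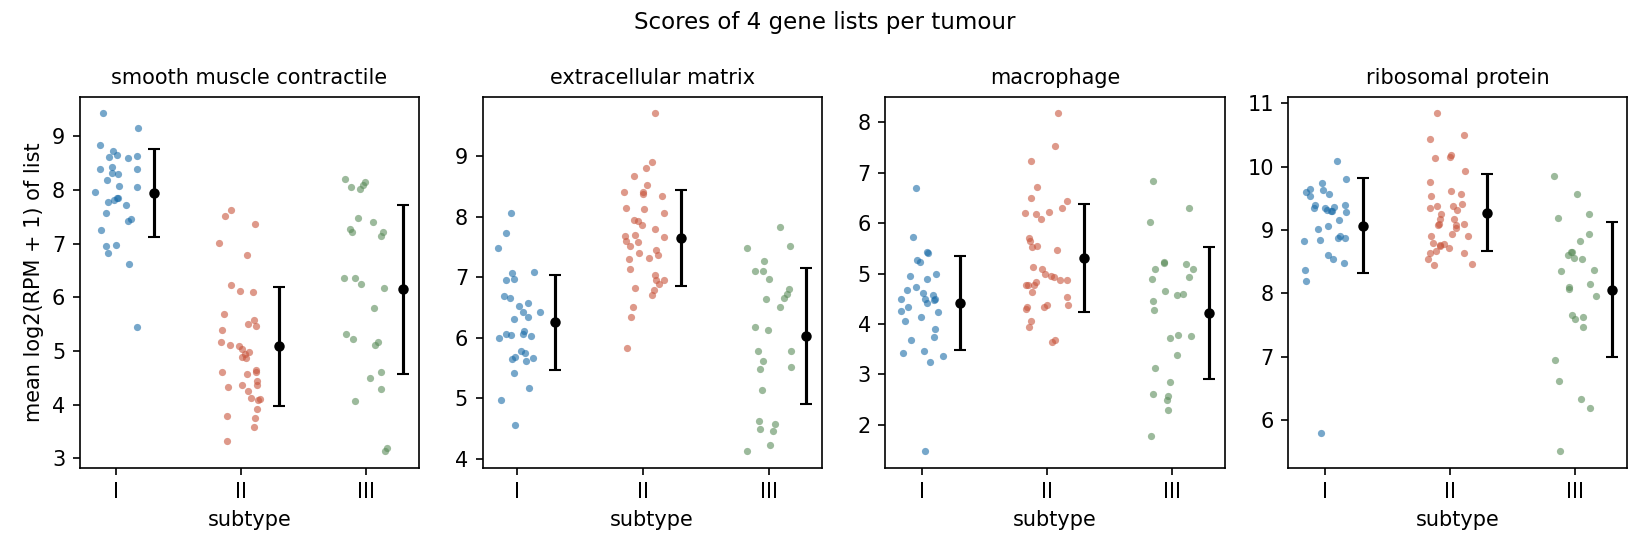
Scores of 4 gene lists, each the mean log2(RPM + 1) of the list, with 1 point per tumour and the mean with its SD beside each subtype. The smooth muscle means are 7.95, 5.09 and 6.15 in subtypes I, II and III, and the ribosomal protein means 9.07, 9.27 and 8.06.

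LMOD1 is a marker that the study chose on these tumours, so its direction is not independent evidence. LMOD1 had medians of 234, 4.04 and 25.6 RPM in subtypes I, II and III.

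Subtype I against subtype III separated many more genes, with smooth muscle genes again higher in subtype I. The smooth muscle score of subtype III was 6.15 ± 1.57 (SD, n = 26), and the difference of 1.80 had an adjusted p of 8.1e-05 (permutation test). MYH11 was higher by 4.82 (SE 0.65), CNN1 by 3.97 (SE 0.60) and LMOD1 by 3.48 (SE 0.49). S100A6, a calcium-binding protein, was higher by 3.68 (SE 0.42) and PLP2 by 3.53 (SE 0.39). The highest genes in favour of subtype III were ENOX1 at 3.25 (SE 0.41), GPR85 at 3.16 (SE 0.44), C2orf15 at 3.06 (SE 0.42), SAMD7 at 3.04 (SE 0.47), HAS2, a hyaluronan synthase, at 3.03 (SE 0.38) and NOX4, an NADPH oxidase, at 3.02 (SE 0.36). In all, 3377 genes were higher and 3100 lower in subtype I.

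Of 40 ribosomal protein genes 27 were higher in subtype I than in subtype III and 2 lower, and 28 and 2 when adjusted over the list alone. RPL32 was higher by 2.06 (SE 0.30) and RPS16 by 1.98 (SE 0.28). Of 19 oxidative phosphorylation genes 11 were higher and none lower, with the same counts when adjusted over the list alone, among them NDUFS3 at 2.35 (SE 0.35) and COX4I1 at 2.01 (SE 0.29). Of 12 MHC class I genes 6 were higher and none lower, with the same counts when adjusted over the list alone. NLRC5, the activator of MHC class I genes, was higher by 2.45 (SE 0.39) and the immunoproteasome subunit PSMB9 by 2.34 (SE 0.39). Of 25 smooth muscle genes 19 were higher and 1 lower, with the same counts when adjusted over the list alone. ENO1, a glycolytic enzyme, was higher by 3.15 (SE 0.53), and ATF4, a stress-induced transcription factor, by 2.08 (SE 0.32). The camera test called these 4 lists, smooth muscle and ribosomal protein genes at adjusted p = 9.87e-08, oxidative phosphorylation at 0.0037 and MHC class I at 0.0249. None was called with an estimated correlation, where the adjusted p was 0.517, 0.727, 0.727 and 0.75.

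The split of calls between directions moved with the scaling and with the libraries used. As deposited 52.1% of the called genes were higher in subtype I than in subtype III, and with median of ratios scaling 37.7% (2601 higher, 4300 lower). The median log2 fold change of all genes moved from 0.00 to -0.21, and to -0.12 with RNF168 left out of the total. Median of ratios scaling flipped the median of the extracellular matrix list from 0.18 to -0.08, but relative to the median of all genes it stayed above 0, at 0.13. Relative to that median the ribosomal protein list stood at 0.95 and the smooth muscle list at 1.59, against 1.17 and 1.63 as deposited. In the 66 libraries of at least 500000 tags with RNF168 under 20%, rescaled without RNF168, 1181 genes were higher and 3993 lower, and the median of all genes was -0.26. There 15 smooth muscle, 21 ribosomal protein, 7 oxidative phosphorylation and 4 MHC class I genes were higher, and 1 oxidative phosphorylation gene was lower. Relative to the median of all genes the list median moved from 1.63 to 1.79 for smooth muscle, from 1.17 to 0.93 for ribosomal protein, from 1.06 to 0.59 for oxidative phosphorylation and from 0.64 to 0.36 for MHC class I genes. With differences taken within the number series the scores moved from 1.01 to 0.86 for ribosomal protein (adjusted p = 0.0527, permutation test), from 0.85 to 0.62 for oxidative phosphorylation (adjusted p = 0.123) and from 0.94 to 0.69 for MHC class I genes (adjusted p = 0.168). These no longer passed, while the smooth muscle score did (1.58, adjusted p = 0.00405).

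Subtypes II and III differed in the extracellular matrix, which was higher in subtype II, and, with the number series pooled, in smooth muscle genes, which were higher in subtype III. The extracellular matrix score was 7.65 ± 0.79 (SD, n = 38) in subtype II and 6.03 ± 1.13 (SD, n = 26) in subtype III (adjusted p = 8.1e-05, permutation test), and 37 of the 38 subtype II tumours lay above the subtype III median. LRRC15 was higher in subtype II by 3.89 (SE 0.65), S100A6 by 3.56 (SE 0.41), MMP2, a gelatinase, by 3.18 (SE 0.54), MXRA8 by 3.12 (SE 0.48), METRNL by 3.04 (SE 0.35) and TNFRSF12A, the TWEAK receptor, by 2.98 (SE 0.43). The highest in favour of subtype III were SAMD7 at 3.61 (SE 0.45), TMEM212 at 3.36 (SE 0.41), C2orf15 at 3.28 (SE 0.40), the pseudogene MEIS3P1 at 3.26 (SE 0.43), ACER3, a ceramidase, at 3.19 (SE 0.36) and the pseudogene HSP90AB2P at 3.17 (SE 0.45). Tags of a pseudogene may be shared with its parent gene. In all, 3426 genes were higher and 3367 lower in subtype II.

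Of 20 extracellular matrix genes 18 were higher in subtype II than in subtype III and none lower, with the same counts when adjusted over the list alone, among them FBN1, encoding fibrillin, at 2.96 (SE 0.39) and COL5A1 at 2.69 (SE 0.41). Of 25 smooth muscle genes 13 were lower in subtype II and none higher, with the same counts when adjusted over the list alone, and the score differed by 1.06 (adjusted p = 0.0107, permutation test). Within the low series that score difference was -1.19 (adjusted p = 0.0668) and within the high series -0.03 (adjusted p = 0.951). The difference weighted within the number series was -0.65 (adjusted p = 0.203, permutation test), so the call was lost once the series were taken into account, while the extracellular matrix score kept it (1.75, adjusted p = 0.000135). Of 40 ribosomal protein genes 30 were higher in subtype II and none lower, and 31 when adjusted over the list alone, RPS16 by 2.00 (SE 0.27). Of 18 macrophage genes 12 were higher and none lower, with the same counts when adjusted over the list alone, LAPTM5 by 2.59 (SE 0.42) and CD14 by 2.29 (SE 0.41). Of 12 MHC class I genes 8 were higher, of 19 oxidative phosphorylation genes 8, of 10 unfolded protein response genes 5 and of 14 hypoxia and glycolysis genes 4, with none lower and the same counts when adjusted over the list alone. ENO1 was higher by 2.97 (SE 0.51) and ATF4 by 2.01 (SE 0.31). Of 8 adipocyte genes 6 were lower in subtype II, and 7 when adjusted over the list alone, and 5 of 10 hormone receptor and uterine genes were lower in both counts, among them EMX2, ESR1, the oestrogen receptor, and PGR, the progesterone receptor, by 1.79 (SE 0.29), 1.68 (SE 0.40) and 1.54 (SE 0.37) in favour of subtype III. ESR1 and PGR lay near the floor, with medians of 0 RPM in subtype II and 5.12 and 4.17 RPM in subtype III. Such levels were not told apart from the raised tags of silent genes in subtype III.

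The camera test called 10 lists between subtypes II and III. Ribosomal protein (adjusted p = 4.25e-12), extracellular matrix (1.22e-07), macrophage (0.00465), oxidative phosphorylation (0.00465), MHC class I (0.00687), unfolded protein response (0.0217) and hypoxia and glycolysis genes (0.0318) were higher in subtype II. Smooth muscle (0.000908), adipocyte (0.0217) and hormone receptor genes (0.0368) were higher in subtype III. None was called with an estimated correlation, where the adjusted p ran from 0.488 to 0.75. As deposited 50.4% of the called genes were higher in subtype II, and with median of ratios scaling 34.2% (2430 higher, 4668 lower). The median of all genes moved from 0.00 to -0.23, and to -0.11 with RNF168 left out of the total. Relative to that median the ribosomal protein list stood at 1.15 and the extracellular matrix list at 1.42. In the 66 libraries named above 1129 genes were higher and 3997 lower, and the median of all genes was -0.24. There 13 extracellular matrix, 22 ribosomal protein, 5 oxidative phosphorylation, 3 macrophage, 3 unfolded protein response, 5 hypoxia and glycolysis and 0 MHC class I genes were higher in subtype II. In the same libraries 2 macrophage genes and 1 oxidative phosphorylation gene were lower. Relative to the median of all genes the list medians moved from 1.33 to 0.82 for macrophage, from 0.99 to 0.55 for MHC class I and from 1.41 to 1.03 for ribosomal protein genes. Weighted within the number series the macrophage score no longer passed (0.76, adjusted p = 0.057, permutation test).

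Genes above both other subtypes numbered 406 for subtype I, 311 for subtype II and 2492 for subtype III. The count for subtype III fell to 605 with the olfactory receptor total as a covariate. That total was itself higher in subtype III, so adjusting for it can remove calls of this subtype whatever their cause. Within the low and high series the counts were 134 and 42 for subtype I, 141 and 53 for subtype II and 839 and 786 for subtype III, from fewer tumours. With edgeR they were 643 for subtype I and 700 for subtype II. Besides the contractile genes, subtype I was marked by AOC3, an amine oxidase of smooth muscle and vessels, MYOM1, a sarcomere protein, RAMP1, a receptor partner of CGRP, and the small heat shock protein HSPB6. Over subtypes II and III these rose by 3.07 and 2.99 (AOC3), 3.38 and 2.99 (MYOM1), 3.66 and 2.96 (RAMP1) and 2.94 and 3.06 (HSPB6). Subtype II was marked by LRRC15, TMEM119, MMP9, PCOLCE, SRPX2, CREB3L1 and PDPN, a membrane glycoprotein. SRPX2 was higher by 2.41 over subtype I (SE 0.35) and by 2.44 over subtype III (SE 0.37), and PDPN by 2.48 (SE 0.51) and 2.26 (SE 0.54). Subtype III was marked by C2orf15, SAMD7, ENOX1, NOX4, HAS2 and ACER3, by KCNJ14, a potassium channel, at 2.92 (SE 0.39) over subtype I and 3.04 (SE 0.37) over subtype II, and by MS4A2, an IgE receptor subunit of mast cells, at 2.88 (SE 0.40) and 3.04 (SE 0.38). For these and the other genes higher in subtype III, higher expression was not told apart from the raised tags of silent genes. The other mast cell genes did not follow MS4A2, and 1 of 5 was called against each of subtypes I and II.

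Both contrasts behind such a count share a group. Lists drawn independently would share 143, 152 and 740 genes, and permuted labels gave 0 in 99 draws. With the shared subtype divided at random between the 2 contrasts, the medians of 10 draws were 178.5, 200 and 1358. Each contrast then used fewer tumours of that subtype, so the fall mixes lost power with the removal of the shared group.

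The permutation tests of list scores called 8 lists for I against II, 7 for I against III and 15 for II against III. The lists scored include 2 study markers as a list, chosen on these tumours, with mean scores of 5.145, 3.825 and 3.435 in subtypes I, II and III. A call of that list is no independent evidence. Of the lists that camera called for I against II, the scores of MHC class II (adjusted p = 0.0574) and ribosomal protein genes did not pass, while those of macrophage (-0.89), hormone receptor (0.55), unfolded protein response (-0.54) and Wnt and ROR genes (-0.53) did. For II against III all 10 lists called by camera passed, among them macrophage (1.08), MHC class I (1.00), ribosomal protein (1.21), hypoxia and glycolysis (0.85) and adipocyte genes (-0.98). Scores passed without a call in camera for adipocyte genes in I against II (0.65, adjusted p = 8.1e-05), and for hypoxia and glycolysis (0.54, adjusted p = 0.0255) and erythroid genes (-0.90, adjusted p = 0.0205) in I against III. For II against III these were MHC class II (0.84, adjusted p = 0.019), cell cycle (0.60, adjusted p = 0.0255), immediate early (0.56, adjusted p = 0.0217) and histone genes (0.60, adjusted p = 0.0183), and the genes altered in leiomyosarcoma (-0.34, adjusted p = 0.0255). Of the 8 adipocyte genes only PLIN4 and LIPE were called in I against II, by 3.74 and 1.26. The median fold change of the 8 was 0.31 and the lowest -0.48, so that score does not show a shared rise of the list. Fewer lists passed for I against III and for II against III with differences weighted within the number series. With the median of the members fewer passed for II against III, so some of these calls depend on such choices.

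The remaining lists had no call in camera. Members higher and lower in subtype I than in II, in I than in III and in II than in III were 0 and 0, 0 and 5, and 3 and 4 of 12 T and NK cell genes. They were 0 and 0, 0 and 1, and 1 and 1 of 9 B and plasma cell genes, 0 and 1, 4 and 2, and 7 and 2 of 14 endothelial genes, and 1 and 0, 1 and 3, and 1 and 4 of 9 pericyte genes. For 19 cell cycle genes they were 0 and 0, 4 and 2, and 6 and 0, for 16 interferon response genes 0 and 0, 2 and 3, and 3 and 2, and for 14 immediate early genes 0 and 0, 2 and 1, and 4 and 0. For 13 skeletal muscle genes they were 2 and 1, 2 and 4, and 2 and 5, for 11 epithelial genes 0 and 0, 1 and 0, and 0 and 1, and for 5 Schwann and neural genes 0 and 1, 0 and 2, and 1 and 2. For 5 replication-dependent histone genes they were 0 and 0, 2 and 1, and 3 and 0, and for 10 genes recurrently altered in leiomyosarcoma 2 and 1, 2 and 3, and 1 and 4. Among 4 erythroid genes, too few for camera, only SLC4A1 was called, higher in subtype III by 2.18 over subtype I (SE 0.45) and 1.97 over subtype II (SE 0.43). The endothelial genes moved in opposite directions, EMCN higher in subtype III than in I by 2.39 (SE 0.38) and ENG higher in subtype II than in III by 1.59 (SE 0.32). Among the altered genes ATRX was higher in subtype III than in subtypes I and II by 1.86 (SE 0.35) and 1.17 (SE 0.34), while MED12 was lower, with 1.76 in favour of subtype I (SE 0.31) and 1.16 in favour of subtype II (SE 0.29). Adjusted over the list alone, 3 B and plasma cell genes and 1 histone gene were lower in subtype I than in II, 3 endothelial genes were higher in subtype I than in III, and 2 interferon response genes were higher in subtype II than in III, with the other counts of these lists unchanged. Counts not given above followed for lists called in only some contrasts. In subtype I against III they were 4 and 3 of 18 macrophage genes, 4 and 2 of 20 extracellular matrix genes, 1 and 2 of 10 hormone receptor and uterine genes and 2 and 0 of 10 unfolded protein response genes. Wnt and ROR genes had 1 and 2 in I against III and 5 and 1 in II against III, and in I against II 1 and 0 of 12 MHC class I and 0 and 1 of 19 oxidative phosphorylation genes were called. In the order used before they were 0 and 1, 2 and 1, and 4 and 0 of 10 MHC class II genes, 1 and 2, 4 and 0, and 4 and 0 of 14 hypoxia and glycolysis genes, and 2 and 0, 2 and 4, and 0 and 6 of 8 adipocyte genes. No member of the mitochondrially encoded list was in the table.

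Tumours of subtype I resembled their own group most. The mean silhouette width over the 1500 most variable genes was 0.20 ± 0.08 (SD, n = 31) in subtype I, 0.15 ± 0.10 (SD, n = 38) in subtype II and 0.14 ± 0.19 (SD, n = 26) in subtype III, and 1, 5 and 8 tumours lay below 0. Within subtype III the smooth muscle score rose with the cell cycle score (Pearson r = 0.598, p = 0.00125, adjusted p = 0.0113; Spearman rho = 0.608, p = 0.00124, adjusted p = 0.0112; permutation tests, 9 relations), and r was 0.585 without the 2 tumours farthest from the median. Given the number of genes detected it no longer passed (partial r = 0.511, adjusted p = 0.0724). With the extracellular matrix score in subtype III r was 0.516 (p = 0.00759, adjusted p = 0.024) and rho 0.476 (p = 0.0148, adjusted p = 0.0665). With the macrophage score in subtype I r was 0.478 (p = 0.008, adjusted p = 0.024) and rho 0.381 (p = 0.0359, adjusted p = 0.108). Without the 2 farthest tumours these fell to 0.371 (p = 0.0735) and 0.230 (p = 0.231), and neither passed. The lowest smooth muscle and macrophage scores in subtype I came from 1 library with 80.0% of its tags on RNF168. No relation was adjusted for the share of RNF168, which lowers all scores of a library together. The other 6 relations had adjusted p of 0.419 or more.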

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

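The alternatives that use A or T runs, RNF168, depth, genes in 50000 tags or the olfactory receptor total were added after seeing the data; the others were chosen before. No paired analysis was possible because the labels carry no replicate numbers shared between groups. For values below, the cause was not tested, except that the number series, the library subsets and the genes without runs use fewer samples or genes. Counts of genes beyond 1.5 times the count in the report are given by setting.

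With the SAM statistic with 100 permutations the counts were I against II higher 976, I against II lower 1030, above both in I 666, above both in II 528. With the edgeR quasi-likelihood test on recovered tags the counts were I against II higher 1149, I against II lower 1422, above both in I 643, above both in II 700. With the values within the middle number series the counts were I against II higher 286, I against II lower 179. With the values within the high number series the counts were I against II higher 92, I against III higher 556, I against III lower 1551, II against III higher 1006, II against III lower 1088, above both in I 42, above both in II 53, above both in III 786. With genes with no A or T run of 12 bases or more the counts were I against II higher 376, I against II lower 379, I against III higher 1462, I against III lower 1968, II against III higher 1383, II against III lower 2028, above both in I 235, above both in II 178, above both in III 1600. With pseudocount 0.1 the counts were I against II lower 357, above both in II 186. With quantile normalization the counts were I against II lower 999, above both in II 467. With the values within the low number series the counts were I against II lower 205, I against III higher 618, I against III lower 1015, II against III higher 948, above both in I 134, above both in II 141, above both in III 839. With libraries of at least 500000 tags the counts were I against II lower 1018, I against III higher 1162, II against III higher 1152. With libraries with RNF168 under 20 percent the counts were I against III higher 1032, II against III higher 1005, above both in I 238, above both in II 200. With deep libraries with RNF168 under 20 percent and left out of the total the counts were I against III higher 1181, II against III higher 1129, above both in I 260. With the olfactory receptor total as a covariate the counts were I against III lower 1357, II against III lower 795, above both in III 605.

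The number of lists called became 2 for I against II with correlation estimated per list, 13 for I against II with no filter on low values, 5 for I against II with deep libraries with RNF168 under 20 percent and left out of the total, 0 for I against III with correlation estimated per list, 0 for II against III with correlation estimated per list. For list scores it became, from 7 for I against III and 15 for II against III, 11 for I against III with quantile normalization, 3 for I against III with weighted difference within number series, 8 for II against III with median instead of mean of the members, 9 for II against III with weighted difference within number series.

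Lists with no call in camera that turned direction are given with their adjusted p. With pseudocount 0.1 these were endothelial I against III (0.9), skeletal muscle I against III (0.99). With no filter on low values these were Schwann and neural I against II (0.929), T and NK cell II against III (0.828), interferon response II against III (0.829). With quantile normalization these were endothelial I against III (0.953). With specimen number series as a covariate these were macrophage I against III (0.914), endothelial I against III (0.985). With deep libraries with RNF168 under 20 percent and left out of the total these were MHC class I I against II (0.965), interferon response I against II (0.962), endothelial I against III (0.937), genes altered in leiomyosarcoma I against III (0.983), B and plasma cell II against III (0.955).

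Score differences that turned sign are given with their value. With pseudocount 0.1 they were genes altered in leiomyosarcoma I against III (0.0827), T and NK cell II against III (0.108), skeletal muscle II against III (0.0995), epithelial II against III (0.0388). With quantile normalization they were endothelial I against III (-0.0578), interferon response I against III (-0.0321), T and NK cell II against III (0.0123), interferon response II against III (-0.00759). With median instead of mean of the members they were pericyte I against II (-0.00713), MHC class I I against II (0.00781), endothelial I against III (-0.0904), interferon response I against III (-0.112), epithelial I against III (-0.0274), immediate early and stress I against III (-0.000803), genes altered in leiomyosarcoma I against III (0.279), skeletal muscle II against III (0.0948). With weighted difference within number series they were macrophage I against III (-0.0882), endothelial I against III (-0.265), MHC class II I against III (-0.142), interferon response I against III (-0.312), skeletal muscle I against III (-0.235), epithelial I against III (-0.106), Wnt and ROR signalling I against III (0.00965), B and plasma cell II against III (-0.154), interferon response II against III (-0.188).

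Over all tested genes the mean silhouette width was 0.115 in subtype I and -0.0143 in subtype III. In 50000 tags other than RNF168, subtype III had more genes (differences of -707 and -776 for I and II against III). With the wider set of highest genes the difference in their share between subtypes I and II turned to -0.619 percentage points. Given the number of genes detected, the partial correlation of the smooth muscle score was 0.341 with macrophage and -0.0188 with extracellular matrix in subtype I, -0.0734 with extracellular matrix in subtype II, and 0.511 with cell cycle and 0.416 with extracellular matrix in subtype III, and none of these passed the test.

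Of the named genes CNN1 turned to 0.76 for II against III, LAPTM5 to -0.20 and ABCC9 to 0.49 for I against III within the high number series. With the olfactory receptor total as a covariate WNT5A turned to 0.12 and CDH1 to 0.0585 for II against III, and ADIPOQ to 0.23 for I against III. Of the other values of named genes 3639 kept direction and call and 342 kept direction only. Depth limits low genes most, since 1 tag weighs most in the shallowest libraries.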

Other observations

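The 4 tumours without a subtype are given as values only. Their smooth muscle scores ran from 4.08 to 6.06 with a median of 5.48, their extracellular matrix scores from 5.58 to 8.81 with a median of 7.52, and their macrophage scores from 4.58 to 7.49 with a median of 5.53. LMOD1 ran from 0.606 to 55.7 RPM.

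The tests on depth and RNF168 loss in subtype III, the share of genes without runs as deposited, the olfactory receptor covariate and the simulated count for the pair with the fewest genes were chosen after the result was seen; the other tests below were set out before their results. The simulation of a continuum was corrected and run again after its first result was seen, because its random draws had repeated. RNF168 took between 0.0615% and 80.0% of a library's tags. A candidate explanation is reads of A or T runs placed on transcripts that hold such runs. Its transcript has a run of 33 T, and of the 50 genes that rose most closely with it 29 had a run of 20 bases or more, 58% against 11.7% of tested genes, a ratio of 4.95 (Fisher's exact test, p = 4.47e-15). The 50 were drawn from genes with a mean of at least 5 RPM, while the 11.7% covers all tested genes with a sequence. Genes that vary together are also not independent draws, which the test takes them to be. LRRC16A, S1PR2, INADL and SLC4A1, noticed after their values were seen, have runs of 28, 37, 25 and 28 bases, but TPTE2P2, a pseudogene with medians of 526, 427 and 2874 RPM in subtypes I, II and III, has none above 9. No biological explanation for RNF168 was tested, and levels of SLC4A1 in the erythroid list carry the same limit.

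Genes in both directions separated subtype III, and only the real split, 1 of 100, gave as many for I against III (6477, highest other 1) and for II against III (6793, highest other 683), which does not bear on chance because the labels came from clustering these values. For genes higher in subtype III the division into low, middle and high series is argued against as the only cause. Within the low and high series their median fold change was at least 0.906 times its pooled value. They were chosen on largely the same tumours, which can raise that ratio, but fits within each series alone still called 839 and 786 genes. Subtype III tumours often had neighbouring specimen numbers within a series. A finer batch of that kind was not tested and stays open. For genes lower in subtype III the pooled medians were -1.282 against subtype I and -1.23 against subtype II. They were -0.9991 and -0.9409 within the low series and -1.197 and -1.276 within the high series. A contribution of the series to the lower genes stays open. Reads on genes with A or T runs are argued against as the only cause, since as deposited 1022 of 8016 genes without a run of 12 bases were higher in subtype III than in both others. That share, 12.7%, was below the 24.1% of the other 6094 tested genes, so a contribution stays open (rescaled to their own total, which raises the share, genes without runs had 1.13 times the share of all genes). The other 6094 include genes of unknown run length, since 95.4% of tested genes had a transcript sequence.

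In the 66 deeper libraries, rescaled without RNF168, the median fold change of genes lower in subtype III was at most 0.446 times its value and that of genes higher in subtype III at least 1.07 times. Relative to the median of all genes, which the rescaling moved, the ratios against subtypes I and II were 0.651 and 0.636 for the lower genes and 0.858 and 0.913 for the higher ones. Shallow libraries and libraries rich in RNF168, which this subset leaves out, are thus argued against as the only cause for the higher genes. These genes were chosen on data that include the 66 libraries, which can raise the ratios. The fit on the 66 libraries alone still called 3238 genes higher in subtype III than in both others. Depth was not made equal between the subtypes in this subset, so a contribution of depth to the higher genes stays open. Depth and tags lost to RNF168 stay open for the lower genes. For the higher genes, genomic DNA or unspliced RNA stays open, since 4 families silent in most tissues were at least 3.60 times higher in the median of subtype III. With the olfactory receptor total as a covariate 605 genes were above both others in place of 2492. That total itself differed by subtype, with medians of 9.89, 8.57 and 55.5 RPM in subtypes I, II and III. On the log2 scale the adjusted p was 6e-05 for I against III and 3.75e-05 for II against III (permutation test). Adjusting for it can remove calls of subtype III whatever their cause, so the fall to 605 does not decide between causes. A difference of the tumours themselves, named by the subtype label, also stays open and was not tested apart from these.

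Between subtypes I and II 1 of 100 splits, the real one, gave as many genes (1222, highest other 9). For labels made by clustering these values this does not bear on chance, and it does not show separate kinds of tumour. Simulated tumours drawn from 1 continuous distribution with the covariance of these samples and divided into 3 by k-means gave as many genes in at least 1 contrast as k-means on the real values (8316) in 19 of 20 simulations, with a median of 10230.5. In 20 of 20 simulations the pair of groups with the fewest genes had at least the 1222 of subtypes I and II, and in 19 of 20 at least the 1483 of such a pair from k-means on the real values, with a median of 5195 and a lowest value of 1448. A continuum divided into 3 could therefore give a count of this size for a pair. The covariance used includes any difference between separate kinds of tumour, so such kinds could reach these counts too. The simulation thus does not decide between a continuum and separate kinds. k-means on the real values put 30 of 31 subtype I tumours in 1 cluster and 30 of 38 subtype II tumours in another, while subtype III was spread over the clusters as 11, 10 and 5. The cluster with 10 subtype III tumours held only 1 of subtype I and 1 of subtype II, so it was mostly subtype III.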
